A study of Homo sapiens with 6 samples.

How the data were processed

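RNA was measured in 6 libraries of human proerythroblasts at day 5 of erythroid culture, 2 each for a non-targeting hairpin (shNT), a hairpin against TFAM and a hairpin against PHB2. Libraries were made from total RNA with a TruSeq kit and sequenced on an Illumina NextSeq, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The columns of the tables were matched to samples by hairpin target and number, and 0 columns were left unmapped. All 6 columns carry the name of the same run, so no batch could be told from the labels.

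The authors deposited a table of raw read counts per gene symbol and a table of RPKM values (read counts scaled to transcript length and to the mapped reads of a library). Per the submitters' processing notes, TopHat, DESeq and the build hg19 were used. The counting program, the annotation, the use of strand and all versions are not given in the sources used here. The counts are whole numbers with 24729 gene symbols. The deposited RPKM values are not a fixed multiple of the counts. In 86.7% of the 9015 genes with at least 50 counts in every library, the ratio of CPM to RPKM stayed within 1.2-fold over the libraries. The reference at hand is of another build than hg19, so only gene symbols were used and no positions are given. TopHat can place a read of a gene at a processed pseudogene or a near-identical copy, which lowers or splits the counts of multigene families.

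The count test used edgeR 4.0.16 in R 4.3.3 on the counts as deposited. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 12528 genes and set aside 12201, of which 6751 had no count in any library. Libraries were scaled by TMM (factors from 0.990 to 1.03). All 6 libraries entered 1 quasi-likelihood fit with a mean per group, 3 residual degrees of freedom and 2.86 prior degrees of freedom. The common biological coefficient of variation was 22.5%. Each contrast was tested with glmQLFTest (2-sided) and the p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors are the fold change divided by the square root of the F statistic. The fit shares 1 estimate of the spread between groups, although the shNT libraries were much closer to each other than the knockdown libraries. Log2 CPM values use a prior count of 2.

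Depth ran from 4726644 to 9208853 counts, a ratio of 1.95 between the deepest and shallowest library. Ratios of genes with 1 to 3 counts in a group are given with exact Clopper-Pearson intervals at 95%, and against a group with 0 counts a bound was set with 3 counts over the group. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. Counts of replicate libraries differed by more than sampling noise. The chi-square per degree of freedom over genes with at least 20 counts was 2.67 in shNT, 26.2 in shTFAM and 32.2 in shPHB2, so none was taken for a repeat deposit of another, which does not show that they are independent.

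Before the data were examined, 29 gene lists with 881 entries were fixed, and 862 entries matched the table. They cover mitochondrial functions, stress responses, erythroid maturation, other blood lineages, the cell cycle and metabolism. Of the 13 genes encoded by mitochondrial DNA 0 matched the table, and they are not analysed here. Results against shNT are given in the report for every list tested, and results of the direct contrast for the lists called. The lymphoid list had under 3 members with enough counts and was not tested. The targeted genes TFAM and PHB2 were left out of their lists. The other 27 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 27 lists. The preset value assumes that members vary almost independently, and for several lists the estimated correlation was far above it. For none of the 3 comparisons did a camera call hold with the estimated correlation. The smallest adjusted p was 0.628 for shTFAM, 0.487 for shPHB2 and 0.453 for the direct contrast. Fry called 0, 6 and 0 lists, and its mixed version, which takes changes in either direction, called 14, 21 and 11.

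The genes named in the text were chosen by a rule fixed with the lists. It took TFAM, PHB2 and PHB. For each contrast against shNT it took the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of at least 3 whose libraries did not overlap, and 5 and 5 for the direct contrast. It took up to 3 called members of each called list and of 7 lists named beforehand, or the member with the smallest p where none was called. Symbols beginning with LOC were treated as lacking a gene symbol and were not named.

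The fit was tested on simulated data with the real means, library sizes and dispersions, over 12359 genes that passed the filter, with the changed genes drawn from those expected to have at least 20 counts in every library. In the simulated comparison of shTFAM with shNT, 18 of 100 genes changed 2-fold and 86 of 100 changed 4-fold were called, with 9 unchanged genes among 113 calls. In that of shPHB2 with shNT, 18 of 100 and 86 of 100 were called, with 13 unchanged genes among 117. A simulated shift of -0.5 in the mitochondrial ribosome list was called by camera at an adjusted p of 1.23e-27, with 0 calls among the other lists. These simulations draw genes independently, so they do not test the preset correlation.

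Alternatives fixed beforehand were median-ratio and upper-quartile scaling, scaling without the 10 globin genes, no filter or a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, and a test against a 1.5-fold change. Further ones were log2(RPKM + 1) and log2(RPKM + 0.1) with limma, the first also with a filter of RPKM of at least 1, a fit of the 2 groups only, the replicate number as a block, stricter thresholds, and leaving out each library in turn. A fit that leaves out a library assumes that the lone library of its group varies like the others. The closing section gives their effect. Groups of 2 are too small for counts of other splits of the samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.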

Results

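Proerythroblasts are the earliest recognisable precursors of red blood cells. Here they were grown from human adult CD34+ blood stem and progenitor cells, and their RNA was sequenced at day 5 of erythroid culture. The progenitors carried a lentiviral short hairpin RNA against TFAM (shTFAM), against PHB2 (shPHB2) or against no human gene (shNT). TFAM encodes the protein that packages mitochondrial DNA and drives its transcription. PHB2 encodes a subunit of the prohibitin complex of the inner mitochondrial membrane. Each of the 3 groups had 2 libraries, named here replicate 1 and replicate 2. The deposited columns of the knockdown libraries carry the names sh1 and sh2, so the pair may be 2 hairpins or 2 cultures of the same hairpin. Nothing in the labels says that the libraries came from separate cultures or donors, so the p-values measure only the spread between these libraries, which may be technical.

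The libraries held 8826456 and 9208853 counts for shNT, 7636360 and 7268295 for shTFAM, and 4726644 and 6198347 for shPHB2. The table listed 24729 genes, of which 12528 had enough counts to be tested. The shNT libraries were far closer to each other than the knockdown libraries were. CPM is the read count of a gene scaled to the TMM-adjusted library size. The median standard deviation of log2 CPM between the 2 libraries was 0.0746 in shNT, 0.183 in shTFAM and 0.220 in shPHB2. In a principal component analysis, the first component took 64.3% of the variance. It placed shPHB2 at 87.9 and 38.6, shTFAM at -0.0912 and -27.6, and shNT at -38.9 and -59.9.

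The targeted genes come first because they check the labels. In shTFAM, TFAM stood at 13.9 and 24.8 CPM against 147 and 160 CPM in shNT, 7.94-fold lower (log2 fold change -2.99 ± 0.28 SE, n = 2 libraries per group). The edgeR quasi-likelihood test gave it an unadjusted p of 5.1e-05 and an adjusted p of 0.0960, above the threshold of 0.05, whereas DESeq2 gave an adjusted p of 2.92e-19. Over all alternatives its adjusted p ran from that value to 0.916, the latter without shNT replicate 2. In shPHB2, PHB2 stood at 64.0 and 37.0 CPM against 391 and 395 CPM in shNT, and it fell by 2.97 ± 0.28 on the log2 scale (7.81-fold lower, edgeR adjusted p = 0.0168). Without shNT replicate 1 its adjusted p was 0.184, and without shNT replicate 2 it was 0.256, at log2 fold changes of -2.99 and -2.97. PHB, which encodes the partner subunit of the prohibitin complex, fell 2.12-fold in shPHB2 (-1.08 ± 0.13, adjusted p = 0.0194) and read -0.51 ± 0.13 in shTFAM (adjusted p = 0.194). Each hairpin left the other target nearer to its control level. TFAM read -0.78 ± 0.26 in shPHB2 (adjusted p = 0.0848), and PHB2 read -0.20 ± 0.26 in shTFAM (adjusted p = 0.702).

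**Figure D1:**
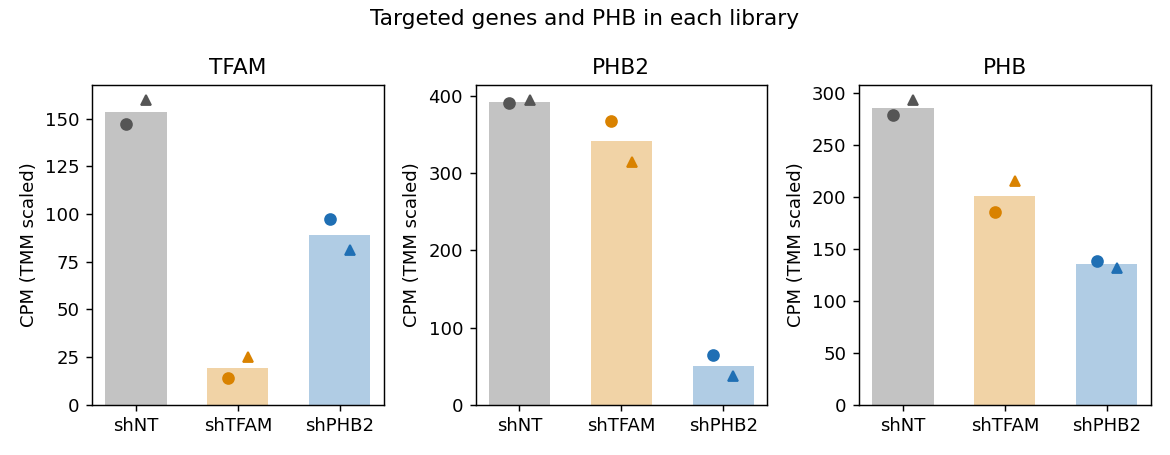
CPM (TMM scaled) of TFAM, PHB2 and PHB on a linear axis, with bars at the mean of the 2 libraries of a group, circles for replicate 1 and triangles for replicate 2. TFAM lies at 13.9 and 24.8 CPM in shTFAM, and PHB2 lies at 64.0 and 37.0 CPM in shPHB2.

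The comparison of shTFAM with shNT asks what loss of the mitochondrial DNA factor does to the transcriptome of these precursors. Of single genes, DOCK9 passed the test. It encodes an activator of the GTPase CDC42, and it fell from 64.7 and 69.1 CPM to 7.94 and 7.48 CPM (8.66-fold lower, -3.11 ± 0.18, n = 2 per group, edgeR adjusted p = 0.0322). DOCK9 stood at 6.83 and 8.74 CPM in shPHB2. Its adjusted p was 0.700 and 0.606 without shNT replicate 1 and 2, and 0.143 and 0.121 without shTFAM replicate 1 and 2. Genes for mitochondrial proteins made in the nucleus lay slightly lower as a body. Over 6 mitochondrial lists pooled, 216 of 244 members had a log2 fold change below 0, with a median of -0.26 and quartiles of -0.40 and -0.13. By edgeR 0 of them passed the test singly, and 64 had an unadjusted p under 0.05 with a value below 0.

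By list, 68 of 74 mitochondrial ribosome genes lay below 0 (median -0.30), as did 25 of 27 genes of mitochondrial DNA maintenance and expression (median -0.31). So did 38 of 43 genes of import and protein quality control (median -0.28), 32 of 37 nuclear genes of respiratory complex I (median -0.25), 35 of 42 of complexes II to V (median -0.24) and 18 of 21 of the TCA cycle (median -0.27). Examples were MRPL17, a protein of the large mitochondrial ribosomal subunit (-0.61 ± 0.12, adjusted p = 0.141), and ATPIF1, the inhibitor of the ATP synthase (-0.77 ± 0.13, adjusted p = 0.126). Further ones were SLIRP, which stabilises mitochondrial messenger RNA (-0.66 ± 0.19, adjusted p = 0.212), NDUFC1 (-0.47 ± 0.13, adjusted p = 0.211) and DLD (-0.38 ± 0.12, adjusted p = 0.242). Camera with a preset correlation of 0.01 placed all 6 lists below other genes, at adjusted p from 6.49e-09 for the mitochondrial ribosome to 0.000817 for the TCA cycle. With an estimated correlation the adjusted p was 0.628 for each of the 6. Without shTFAM replicate 1 the TCA cycle list was no longer called (adjusted p = 0.0806).

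All 30 S phase genes and all 32 G2 and mitosis genes lay below 0 in shTFAM, at medians of -0.54 and -0.54. GMNN, which restrains DNA re-replication, read -0.78 ± 0.25 (adjusted p = 0.241), and KIF20B, a mitotic kinesin, read -0.74 ± 0.24 (adjusted p = 0.243). Camera adjusted p were 2.3e-08 and 3.84e-08 with the preset correlation, and both were 0.628 with an estimated correlation. The shift was mostly in 1 library. The S phase median was -0.86 in replicate 1 and -0.30 in replicate 2.

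In the other direction, 21 of 25 cholesterol synthesis genes lay above 0 in shTFAM (median 0.41, camera adjusted p = 0.000148, and 0.628 with an estimated correlation). TM7SF2, a sterol reductase, read 0.96 ± 0.12 (adjusted p = 0.0971), and adjusted over the list alone 1 member was higher. The list was not called without shTFAM replicate 1 (adjusted p = 0.0644). Of 23 autophagy and mitophagy genes, 17 lay above 0 (median 0.26, camera adjusted p = 0.00555, and 0.628 with an estimated correlation). Among them ULK1, a kinase that starts autophagy, read 0.89 ± 0.14 (adjusted p = 0.110), and 2 members were higher when adjusted over the list alone. The megakaryocyte and platelet list was placed above other genes (camera adjusted p = 0.0191, and 0.745 with an estimated correlation) although its median was 0.08 and its mean -0.11. LAT, an adaptor of platelet and T cell signalling, led it at 1.70 ± 0.20 (adjusted p = 0.0971), and 4 of its 17 members were higher when adjusted over the list alone. Without shNT replicate 2 the direction of that list turned, at an adjusted p of 0.424. It was not called without shTFAM replicate 1 (0.331) or without shPHB2 replicate 1 or 2 (0.109 and 0.283).

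The erythroid lists were not called in shTFAM, and the 2 libraries lay on opposite sides of shNT in the globin, erythroid membrane and heme synthesis lists. The globins and AHSP had a median of -0.71 in replicate 1 and 1.43 in replicate 2, relative to shNT (camera adjusted p = 0.413 for the group). Over both libraries 9 of the 11 members lay above 0 and 2 below. AHSP itself was lower in both libraries, at 38.9 and 162 CPM against 235 and 261 in shNT. HBZ, an embryonic globin, read 2.20 ± 0.67 (adjusted p = 0.231) on 91 counts against 24. ALAS2, the erythroid enzyme that starts heme synthesis, stood at 783 and 1175 CPM against 326 and 374 in shNT (1.48 ± 0.31, adjusted p = 0.157). CBFA2T3, a transcriptional corepressor, read 0.88 ± 0.20 (adjusted p = 0.171), and SLC14A1, the urea transporter of red cells, read 1.24 ± 0.16 (adjusted p = 0.0971). Without replicate 1 the globin list lay higher (adjusted p = 4.84e-11), and without replicate 2 it lay lower (adjusted p = 0.00447). The erythroid membrane list split the same way, at adjusted p of 0.00168 and 0.00047, and had a group median of 0.08 against a downward direction by camera (adjusted p = 0.936). Adjusted p were 0.843 for heme synthesis and 0.224 for erythroid transcription factors.

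Targets of the stress factor ATF4 were not called in shTFAM (median -0.17, or -0.13 with members at 0 counts put at their bound, and mean 0.09, camera adjusted p = 0.507), but without shTFAM replicate 2 they lay lower (0.0179). DDIT4, an inhibitor of mTORC1 signalling, read 1.13 ± 0.35 (adjusted p = 0.231). The interferon-stimulated list had a median of 0.28 (adjusted p = 0.227), and RSAD2, an antiviral enzyme, read 1.33 ± 0.29 (adjusted p = 0.159). Granulocyte and monocyte markers were not called (median -0.42, adjusted p = 0.936), with library medians of 1.26 and 0.85 log2 CPM in shTFAM and 2.58 and 0.57 in shNT. Without shNT replicate 1 they lay higher (0.0245), and without shNT replicate 2 lower (0.00011). Among the remaining lists, adjusted p were 0.0516 for stem and progenitor cell and for p53 targets, both close to the threshold, 0.150 for ketone body and fatty acid oxidation, 0.227 for the cytosolic ribosome, and 0.468 for hypoxia-inducible genes. They were 0.507 for glycolysis, for NRF2 and antioxidant genes and for the mast cell, basophil and eosinophil list, and 0.669 for iron handling and Fe-S assembly. The stem and progenitor list was called without shNT replicate 1 (0.0142), shTFAM replicate 2 (0.0115) or shPHB2 replicate 1 or 2 (0.0384 and 0.0375). The p53 list was called without shNT replicate 2 (0.0195), shTFAM replicate 1 (0.00682) or shPHB2 replicate 1 or 2 (0.0246 and 0.0404). Median and mean differed in sign for heme synthesis (-0.07 and 0.01), iron handling (-0.04 and 0.11) and glycolysis (-0.03 and 0.24). The cytosolic ribosome was called without shTFAM replicate 2 (0.0396) and without shPHB2 replicate 2 (0.0399).

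At an unadjusted p under 0.05, 2122 genes differed between shTFAM and shNT, 1327 higher and 795 lower. The count of calls rested on the test used: DESeq2 called 457 genes, 355 higher and 102 lower, and the absence of a filter on low counts gave 83. With the replicate number as a block edgeR called 307, 268 higher and 39 lower, but the labels do not say what this number marks. Without shNT replicate 1 or 2, or without shTFAM replicate 1 or 2, edgeR called 0 genes, and without either shPHB2 library it called 2.

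The comparison of shPHB2 with shNT asks the same of the prohibitin complex. It called 1997 of 12528 genes, 1073 higher and 924 lower, and 1126 of them changed at least 2-fold (801 higher, 325 lower). Which direction held more calls depended on the fit. Within edgeR, upper-quartile scaling gave 1289 higher and 700 lower and median-ratio scaling 1003 and 972. Limma-voom gave 683 and 710, and in limma fits, which change both scale and test, log2(RPKM + 1) gave 831 and 1285, log2(RPKM + 0.1) gave 1037 and 1438, and log2(RPKM + 1) with the RPKM filter gave 707 and 1204. The median log2 fold change of all genes was 0.05 here, 0.13 with upper-quartile scaling and -0.06 with the RPKM filter, so small changes are relative to the scaling.

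Of 43 tested targets of ATF4, the transcription factor of the integrated stress response, 23 rose and 1 fell (median log2 fold change 1.36), and 26 rose when adjusted over the list alone. DDIT3, which encodes the stress factor CHOP, rose 4.63-fold (2.21 ± 0.20, n = 2 per group, edgeR adjusted p = 0.0168). SLC7A11, the cystine transporter, rose 6.63-fold (2.73 ± 0.26, adjusted p = 0.0168). STC2, a secreted glycoprotein, had 276 counts against 1 in shNT, a ratio of 445 with a 95% counting interval of 79.3 to 17648. Without shNT replicate 1 it was at least 75.6-fold higher (0 control counts, taken as 3 over the group), and without shNT replicate 2 the ratio was 219 (interval 38.9 to 8662). PHGDH, the enzyme that commits glucose carbon to serine, rose from 2.51 and 0.988 CPM to 180 and 509 CPM (7.62 ± 1.18, adjusted p = 0.0255). The list lay above other genes (camera adjusted p = 8e-14, and 0.487 with an estimated correlation). Its median was 0.71 in shPHB2 replicate 1 and 1.70 in replicate 2. PHGDH read 6.66 without replicate 2, and 8.41 without shNT replicate 1.

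ASS1, an enzyme of arginine synthesis, went from 0.228 and 0.220 CPM (2 counts in each shNT library) to 81.9 and 155 CPM (8.95 ± 0.66, adjusted p = 0.0168). ALDH1L2, a mitochondrial folate enzyme, had 82 and 242 counts against 3 and 1 (6.85 ± 0.98, adjusted p = 0.0231), and ADM2, a peptide hormone, had 116 and 404 against 7 and 0 (6.75 ± 1.21, adjusted p = 0.0300). IGFBP2, which binds insulin-like growth factors, had 351 and 146 counts against 3 and 1 (7.66 ± 1.14, adjusted p = 0.0244). MAP1B, a microtubule protein, had 65 and 446 against 3 and 1 (7.45 ± 1.17, adjusted p = 0.0301). With so few control counts these fold changes are imprecise. Without shPHB2 replicate 1, IGFBP2 read 6.54 and MAP1B 8.16, and without replicate 2 they read 8.27 and 5.83, ADM2 5.90 and ALDH1L2 6.17. ADM2 was at least 142-fold higher without shNT replicate 1 (520 counts against 0, taken as 3) and read 5.75 without replicate 2. For the other 3, left with 1 or 3 control counts, log2 ratios of counts are given with their counting intervals. They were 8.06 (5.57 to 13.36) for ALDH1L2, 8.67 (6.19 to 13.98) for IGFBP2 and 8.71 (6.23 to 14.02) for MAP1B without shNT replicate 1. With shNT replicate 2 left out they were 6.42 (4.86 to 8.70), 7.04 (5.48 to 9.32) and 7.08 (5.52 to 9.36). MMP2, a matrix protease, read 6.79 ± 1.33 (adjusted p = 0.0332), and RNASE2, a ribonuclease of eosinophil granules, read 7.14 ± 1.59 (adjusted p = 0.0402). Both were much higher in replicate 1 (212 and 78.7 CPM) than in replicate 2 (28.3 and 5.78 CPM). Without replicate 1 they read 4.67 and 4.26 and were not called (adjusted p of 0.0614 and 0.0695), and without replicate 2 they read 7.60 and 8.04. Without either shTFAM library they were not called (0.0538 to 0.0643). Their log2 ratios of counts were 9.91 (7.43 to 15.22) and 8.38 (5.90 to 13.69) without shNT replicate 1, and they read 5.84 and 6.45 without shNT replicate 2.

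**Figure D2:**
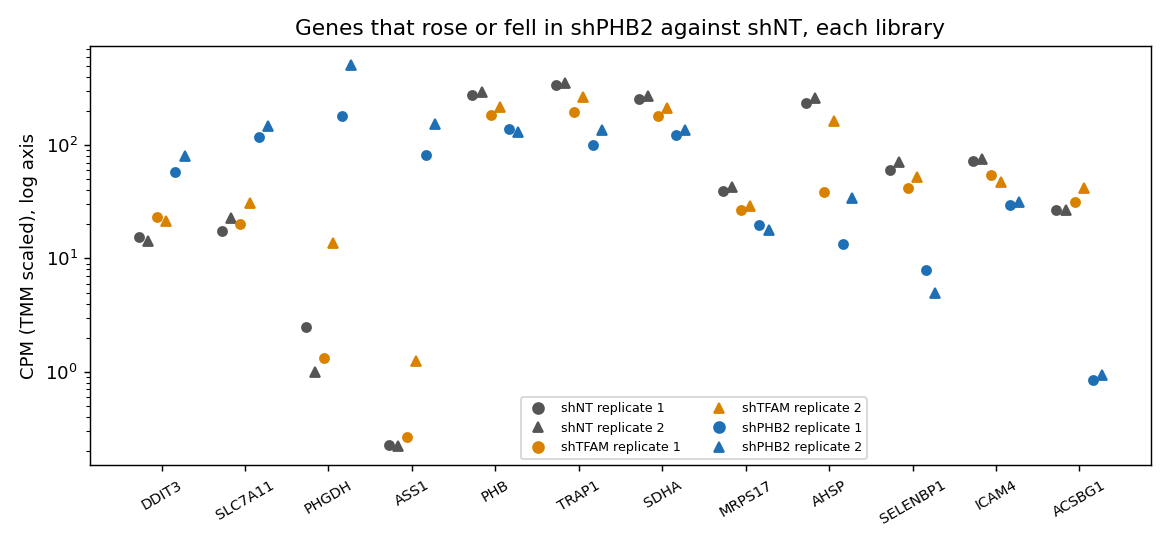
CPM (TMM scaled, log axis) of 12 genes in each of the 6 libraries, with circles for replicate 1 and triangles for replicate 2. ASS1 reaches 81.9 and 155 CPM in shPHB2, SELENBP1 lies there at 7.89 and 5.00 CPM against 60.0 and 71.2 in shNT, and ACSBG1 lies at 0.853 and 0.937 CPM against 26.9 in both shNT libraries.

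Genes of nuclear-encoded mitochondrial proteins lay lower as a group in shPHB2. Of the 244 pooled members, 223 lay below 0, 81 fell and 2 rose, with a median of -0.46 and quartiles of -0.63 and -0.23. In the mitochondrial ribosome list 30 of 74 members fell and 0 rose (median -0.47; 41 fell when adjusted over the list alone). MRPS17, a small-subunit protein, fell 2.18-fold (-1.13 ± 0.14, adjusted p = 0.0194), and MRPS2 and MRPS7 fell by 0.93 and 0.89 on the log2 scale. In import and protein quality control 17 of 43 fell (median -0.50; 22 over the list alone). TRAP1, the mitochondrial chaperone of the HSP90 family, fell 2.93-fold (-1.55 ± 0.22, adjusted p = 0.0226), and TIMM13, a chaperone of the intermembrane space, fell by 0.88. Of genes for mitochondrial DNA maintenance and expression, 9 of 27 fell (median -0.50; 17 over the list alone), among them ELAC2, which cuts mitochondrial transfer RNA (-1.02 ± 0.16), TRMT10C (-0.90 ± 0.13) and PPRC1 (-1.04 ± 0.20).

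In the respiratory chain, 7 of 37 complex I genes fell (median -0.36; 7 over the list alone), among them NDUFS1 (-0.80 ± 0.14), NDUFV1 (-0.76 ± 0.14) and NDUFA10 (-0.55 ± 0.11). For complexes II to V, 11 of 42 fell and 2 rose (median -0.30; 14 and 2 over the list alone). SDHA, the flavoprotein of succinate dehydrogenase, fell 2.03-fold (-1.02 ± 0.14, adjusted p = 0.0227), ATPIF1 fell 2.01-fold and ATP5G1 fell 1.94-fold. The 2 that rose were COX7C (0.79) and COX7A2L (0.58), chosen for naming after their values were seen. Of TCA cycle genes 7 of 21 fell (median -0.50; 16 over the list alone), among them FH (-0.89 ± 0.18) and SUCLG2 (-0.74 ± 0.11). In ketone body and fatty acid oxidation, 7 of 22 fell (median -0.34; 9 over the list alone). Examples were BDH1, which converts β-hydroxybutyrate (-0.76 ± 0.12), ECI2 (-0.59 ± 0.11) and ACAT1 (-0.64 ± 0.12). All 7 lists were called by camera, at adjusted p from 2.58e-12 for the mitochondrial ribosome to 0.0102 for ketone body and fatty acid oxidation. With an estimated correlation the adjusted p was 0.499 for complexes II to V and 0.487 for the others. The rotation test fry called the mitochondrial ribosome (0.0229), mitochondrial DNA maintenance (0.0248), ketone body and fatty acid oxidation (0.0248) and import (0.0318). Without shPHB2 replicate 1, NDUFS1, NDUFV1, NDUFA10, ATP5G1, ELAC2, PPRC1, FH, BDH1 and ECI2 were not called, at adjusted p from 0.0501 to 0.0916.

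The globin, erythroid membrane and heme synthesis lists lay lower in shPHB2. AHSP, the chaperone of alpha globin, fell 10.3-fold, from 235 and 261 CPM to 13.4 and 33.9 CPM (-3.37 ± 0.76, adjusted p = 0.0407). It read -2.90 without replicate 1 and was not called (adjusted p = 0.119), and it read -4.22 without replicate 2. The globin list lay lower (10 of 11 members below 0, median -1.65, camera adjusted p = 0.00012, and 0.487 with an estimated correlation), with AHSP its 1 called member and 9 members lower when adjusted over the list alone. Reads of HBA1 and HBA2, and of HBG1 and HBG2, cannot be assigned with certainty between these near-identical pairs. All globins together took 1.29% and 1.44% of counts in shNT, 0.273% and 0.625% in shPHB2, and 0.844% and 1.84% in shTFAM. In the erythroid membrane and maturation list 9 of 37 fell and 1 rose (median -0.91; 18 and 2 over the list alone; camera adjusted p = 1.44e-07, and 0.487 with an estimated correlation). SELENBP1, a selenium-binding protein abundant in red cells, fell 10.3-fold (-3.37 ± 0.27, adjusted p = 0.0168), ICAM4, the Landsteiner-Wiener blood group protein, fell 2.42-fold (-1.27 ± 0.13), and SLC14A1 rose 2.97-fold (1.57 ± 0.16). In heme synthesis 2 of 17 fell (median -0.53; 9 over the list alone; camera adjusted p = 0.00121, and 0.487 with an estimated correlation). These were ABCB10, a mitochondrial transporter (-1.43 ± 0.31), and TMEM14C, which moves a porphyrin precursor into the matrix (-0.61 ± 0.12). Erythroid transcription factors were not called as a list (median -0.32, adjusted p = 0.0894), and were called without shNT replicate 1 (0.0496) or shPHB2 replicate 2 (0.00213). ZBTB7A fell by 0.66 (adjusted p = 0.0471). ABCB10 was not called without shPHB2 replicate 1 (0.117) or 2 (0.0528), TMEM14C without replicate 1 (0.0501), and ZBTB7A without replicate 1 (0.0929) or either shTFAM library (0.0638). In the same libraries, granulocyte and monocyte markers had a median of 6.32 log2 CPM in replicate 1 and 3.60 in replicate 2, against 2.58 and 0.57 in shNT. The erythroid membrane median was -1.51 in replicate 1 and -0.64 in replicate 2.

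The largest falls outside these lists were of several kinds. ACSBG1, an acyl-CoA synthetase, fell 29.3-fold (-4.87 ± 0.26, adjusted p = 0.0168) on 10 counts against 481. TRIM29, a TRIM-family protein, fell 12.5-fold (-3.65 ± 0.32), LRP1, an endocytic receptor, fell 11.6-fold (-3.54 ± 0.27), and CD70, a ligand of the tumour necrosis factor family, fell 11.1-fold (-3.47 ± 0.43). DNAJA4, a co-chaperone, fell 10.2-fold (-3.35 ± 0.39). The noncoding RNA LINC01215 fell 10.4-fold (-3.38 ± 0.46), and the counting is not stated to use strand, so reads of an overlapping gene on the other strand could be counted with it. Without shPHB2 replicate 1, CD70 read -4.07 and LINC01215 -4.32, and without replicate 2 LINC01215 read -2.78.

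All 30 S phase genes and all 32 G2 and mitosis genes lay below 0 in shPHB2, at medians of -0.68 and -0.97, and 1 and 5 of them fell. CCNE1, a cyclin of S phase entry, fell 3.20-fold (-1.68 ± 0.38, adjusted p = 0.0415), and CCNB1, a mitotic cyclin, fell 2.48-fold (-1.31 ± 0.24, adjusted p = 0.0301). CDC20 and BUB1 fell by 1.49 and 0.91. Without shPHB2 replicate 1 these 4 were not called, at adjusted p of 0.123, 0.0614, 0.0888 and 0.102, nor was BUB1 without either shTFAM library (0.0502 and 0.0503). Adjusted over the list alone, 0 S phase and 23 G2 and mitosis genes fell. Camera adjusted p were 9.2e-07 and 2.32e-10, and 0.499 and 0.487 with an estimated correlation. The S phase median was -1.22 in replicate 1, where the granulocyte and monocyte level was higher, and -0.33 in replicate 2.

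Markers of other blood lineages lay higher in shPHB2. All 19 granulocyte and monocyte members lay above 0 (median 4.97), 5 rose, and 17 were higher when adjusted over the list alone (camera adjusted p = 3.54e-06, and 0.487 with an estimated correlation). MS4A3 rose from 1.82 and 0.110 CPM to 148 and 11.9 CPM (6.35 ± 1.49, adjusted p = 0.0446), TYROBP read 5.86 ± 1.39 (adjusted p = 0.0452) and CD68, a lysosomal protein of macrophages, read 2.42 ± 0.49 (adjusted p = 0.0347). Without replicate 1, MS4A3 read 3.58 and TYROBP 3.36, and neither was called (adjusted p of 0.100 and 0.106), while CD68 read 1.51 (0.0459). Without replicate 2 MS4A3 and TYROBP read 7.24 and 6.72. Their log2 ratios of counts were 9.30 (counting interval 6.82 to 14.61) and 8.44 (5.96 to 13.75) without shNT replicate 1, and they read 5.42 and 4.96 without shNT replicate 2. Without shTFAM replicate 1 the 3 genes were not called (0.0710, 0.0711 and 0.0551), nor without shTFAM replicate 2. In the mast cell, basophil and eosinophil list 5 of 13 rose (median 2.43; 10 over the list alone; camera adjusted p = 0.000293, and 0.487 with an estimated correlation). MS4A2, a subunit of the IgE receptor, had 56 counts against 1, a ratio of 90.3 with a counting interval of 15.6 to 3631. That ratio was 46.0 (7.92 to 1849) without shNT replicate 1, and MS4A2 was at least 14.8-fold higher without shNT replicate 2 (0 control counts, taken as 3). PRG2, an eosinophil granule protein, rose 5.41-fold, and GRAP2 rose 3.18-fold. Without shPHB2 replicate 1, MS4A2 and PRG2 were not called (0.0708 and 0.0557, PRG2 at 1.46), nor were PRG2 and GRAP2 without shTFAM replicate 1 (0.0584 and 0.0532) or 2 (0.0601 and 0.0543). The megakaryocyte and platelet list passed by a small margin (median 0.67, 2 of 17 rose and 1 over the list alone; camera adjusted p = 0.0459, and 0.600 with an estimated correlation). LAT rose 3.16-fold and ITGA2B, the platelet integrin, rose 1.91-fold. The list was not called without shPHB2 replicate 1 (adjusted p = 0.804), shNT replicate 2 (0.812), or shTFAM replicate 1 or 2 (0.146 and 0.142), nor ITGA2B without either shPHB2 library (0.107 and 0.0803).

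Autophagy and mitophagy genes lay higher (5 of 23 rose, 6 over the list alone, median 0.30, camera adjusted p = 0.0146, and 0.487 with an estimated correlation). ULK1 rose 2.14-fold (1.10 ± 0.14), MAP1LC3B, a protein of the autophagosome membrane, rose 2.12-fold (1.09 ± 0.19), and TAX1BP1, a cargo receptor, rose 1.67-fold (0.74 ± 0.12). The list was not called without shPHB2 replicate 2 (0.0738), nor TAX1BP1 without replicate 1 (0.0566). Of 74 cytosolic ribosome genes 67 lay above 0 (median 0.24, camera adjusted p = 0.0297, and 0.751 with an estimated correlation), and RPS27, whose reads can be shared with processed pseudogenes, rose 1.84-fold. Without replicate 1 the direction of this list turned, at an adjusted p of 0.709, and without shNT replicate 2 it was not called (0.128). RPS27 was not called without shPHB2 replicate 1 (0.0937) or shTFAM replicate 1 or 2 (0.0674 and 0.0688). In the interferon-stimulated list 3 of 35 rose and 3 fell (median 0.31, adjusted p = 0.247). XAF1, a pro-apoptotic protein, rose 7.62-fold (2.93 ± 0.20), TRIM22 rose 3.15-fold (1.65 ± 0.34) and LGALS3BP fell 2.04-fold (-1.03 ± 0.18). TRIM22 was not called without shPHB2 replicate 1 (0.0626) or shTFAM replicate 1 or 2 (0.0514 and 0.0529). The adjusted p was 0.0795 for iron handling and Fe-S assembly, which fry called lower (0.0229), 0.139 for p53 targets, 0.173 for cholesterol synthesis, 0.225 for stem and progenitor cell, 0.391 for hypoxia-inducible genes, 0.492 for NRF2 and antioxidant genes, and 0.830 for glycolysis, whose median was -0.13 and mean 0.14. The iron list was called without shNT replicate 1 (0.0439) or either shTFAM library (0.0481 and 0.0474). The stem and progenitor list was called without shNT replicate 1 (0.0486), either shTFAM library (0.0393 and 0.0308) or shPHB2 replicate 2 (0.00854).

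**Figure D3:**
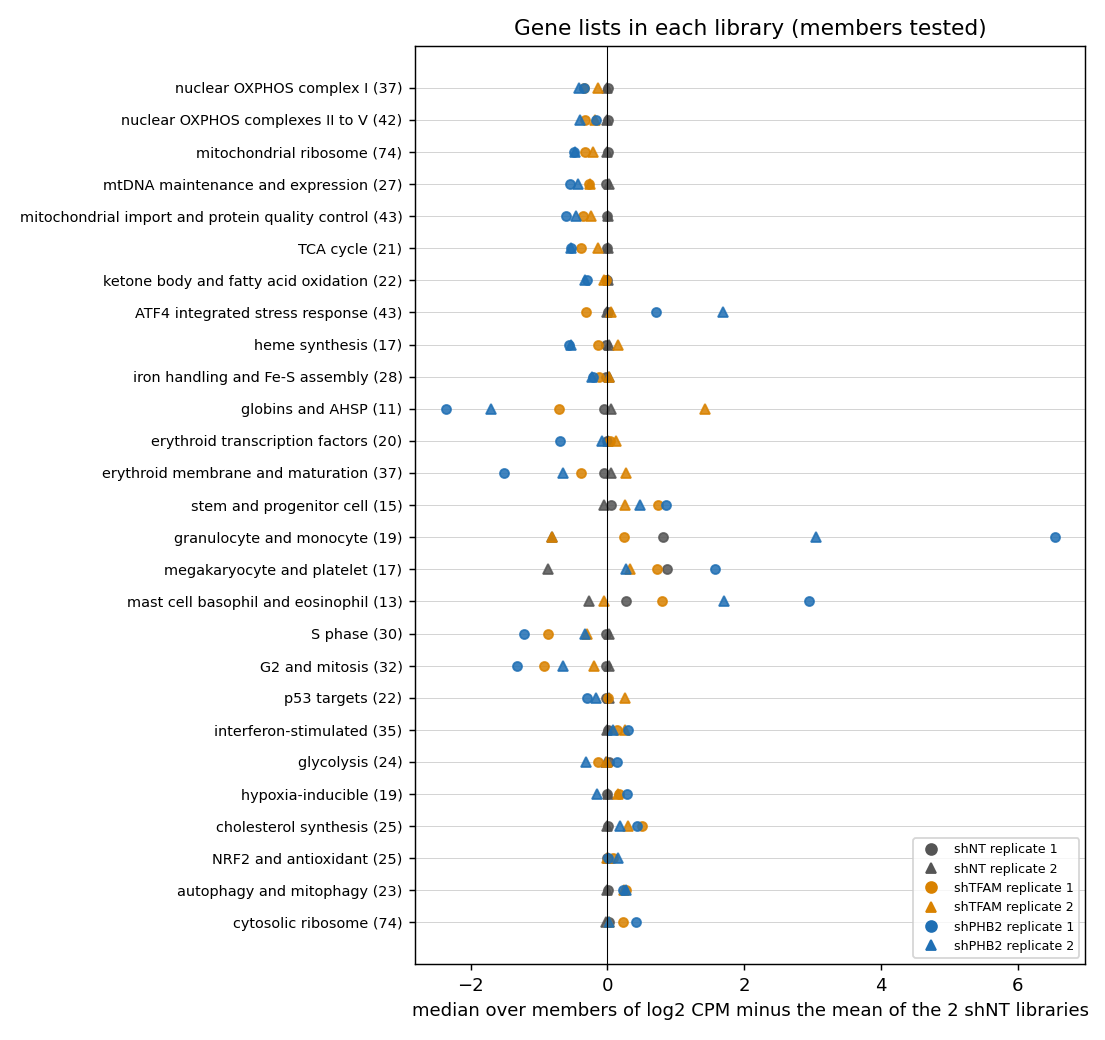
Each row is a gene list with its number of tested members, and each symbol is the median over members, in 1 library, of log2 CPM minus the mean of the 2 shNT libraries. In shPHB2 the granulocyte and monocyte median lies at 6.55 and 3.05 and the ATF4 median at 0.71 and 1.70, and the globin median lies at -0.71 and 1.43 in the 2 shTFAM libraries.

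The count of 1997 calls depends on single libraries. Without shNT replicate 1 or replicate 2, edgeR called 0 genes, without shPHB2 replicate 1 it called 647, and without shPHB2 replicate 2 it called 3682. Of 64 named genes called here, 0 remained called without either shNT library, 53 without either shTFAM library, 36 without shPHB2 replicate 1 and 62 without replicate 2, while all 64 kept their direction in each of these.

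The direct comparison of shPHB2 with shTFAM asks which changes differ between the knockdowns. It called 31 genes, 15 higher and 16 lower in shPHB2, and 2466 had an unadjusted p under 0.05. Its standard errors and p-values also draw on the closer shNT pair, which is not part of this contrast. A fit of these 2 groups only and limma-voom each called 0 genes, and DESeq2 called 839. ASS1 was higher in shPHB2 by 7.28 ± 0.58 (edgeR adjusted p = 0.0396; 6.55 without shTFAM replicate 1, and a ratio of counts of 469, interval 129 to 3873, without replicate 2), and COLGALT2, a collagen glycosyltransferase, had 293 counts against 3, a ratio of 130 with a counting interval of 44.1 to 635 (200, 35.5 to 7909, without shTFAM replicate 2). AKNA (3.66 ± 0.35), FAM83A (3.26 ± 0.26) and XAF1 (2.48 ± 0.20) were also higher. ACSBG1 was 39.9-fold lower in shPHB2 (-5.32 ± 0.26, adjusted p = 0.0147), and SELENBP1 was 7.38-fold lower (-2.88 ± 0.26). TNS1, a focal adhesion protein, stood at 91.9 and 64.4 CPM in shTFAM, at 12.6 and 7.03 in shPHB2 and at 22.5 and 24.0 in shNT (-3.01 ± 0.32, adjusted p = 0.0474). COLQ, a collagen-tailed anchor of acetylcholinesterase, stood at 32.3 and 37.3 CPM in shTFAM against 7.68 and 6.87 in shPHB2 (-2.26 ± 0.21). PHB2 read -2.76 ± 0.28 (adjusted p = 0.0456), TFAM read 2.21 ± 0.28 (adjusted p = 0.0685) and PHB -0.57 ± 0.13 (adjusted p = 0.123).

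Among lists, ATF4 targets lay higher in shPHB2 than in shTFAM (40 of 43 members above 0, median 1.29, camera adjusted p = 2.66e-32). So did granulocyte and monocyte markers (median 6.29, 1.74e-09) and the mast cell, basophil and eosinophil list (median 2.02, 1.86e-05). Erythroid membrane genes (34 of 37 below 0, median -0.80, 1.01e-13), the globins (median -2.32, 1.71e-09), heme synthesis (median -0.51, 1.86e-05) and erythroid transcription factors (median -0.41, 0.000167) lay lower. The mitochondrial ribosome (median -0.22, 1.86e-05), import (-0.33, 0.000309), the TCA cycle (-0.34, 0.000764), mitochondrial DNA maintenance (-0.21, 0.00642) and ketone body and fatty acid oxidation (-0.18, 0.0420) did too. So did p53 targets (-0.46, 4.09e-05), G2 and mitosis genes (-0.38, 0.000147) and iron handling (-0.17, 0.0420). With an estimated correlation none of the 15 calls held, and the adjusted p was 0.453 or more for every list. Without shTFAM replicate 2 the call was lost for G2 and mitosis (0.440), the TCA cycle (0.0716), ketone body oxidation (0.0652) and mitochondrial DNA maintenance (0.0567). Without shPHB2 replicate 1 it was lost for G2 and mitosis (0.423), iron handling (0.0596) and mitochondrial DNA maintenance (0.0520), and without replicate 2 for ketone body oxidation (0.161) and iron handling (0.0815). Without either shNT library, or without either shTFAM library, edgeR called 0 genes, and without shPHB2 replicate 1 or replicate 2 it called 92 and 534.

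Of the 1073 genes that rose in shPHB2, 988 (92.1%) also lay above 0 in shTFAM, with a median of 0.75 there against 1.66 in shPHB2. Of the 924 that fell, 879 (95.1%) lay below 0, with medians of -0.37 and -0.85. Both sets were chosen against the same shNT libraries, so 100 simulations, added after these values were seen, left shTFAM unchanged and gave shPHB2 its own means. They put 59.8% of rising and 62.8% of falling genes on the same side in shTFAM, at medians of 0.11 and -0.08, and drew genes independently. These shares come from larger sets, since the simulations called a mean of 1747 rising and 1451 falling genes in shPHB2. Pearson's r of the fold changes across all 12528 genes, which are not independent replicates, was 0.560. Both comparisons use the same shNT libraries, and 100 simulations of unchanged groups against them gave a mean r of 0.460, from 0.420 to 0.516. The covariance was 0.459 against a simulated mean of 0.111, a difference of 0.348. Same signs were seen in 78.0% of genes against a simulated 66.2%. Both sets of simulations gave a gene the same spread in every library, although the shNT pair was closer. Its median standard deviation of log2 CPM was 0.0746, against 0.183 in shTFAM and 0.220 in shPHB2. If the shNT pair shows the true spread of the controls, the simulations overstate their noise, and with it the agreement that sharing them brings. If that pair hides variation between cultures, the simulations may understate both. The labels do not settle which. DOCK9 was the 1 gene called in both comparisons by the main fit. For that fit the simulations of unchanged groups gave a mean of 0.16 genes, and independent lists would give 0.0738 among genes that fell. Over the alternatives the number called in both ran from 0 to 353 (DESeq2), with 266 for the replicate number as a block. With 2 control libraries the controls could not be split, so part of any excess may come from sharing them.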

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

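The tests of abundance and length and of depth were fixed before their results were seen, and the other tests of explanations here were chosen only after the result was seen. The direct contrast and its alternatives were fixed before.

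The direct contrast was used to ask which effects of the 2 knockdowns differ, and 12 named genes and 15 lists differed by it. Without any one of the shNT or shTFAM libraries edgeR called 0 genes here, and 0 of the 15 list calls held with an estimated correlation (smallest adjusted p 0.453) or with fry (0.0641). The log2 fold changes of shPHB2 against shTFAM were 7.28 for ASS1, 3.66 for AKNA, 3.26 for FAM83A, 2.48 for XAF1, 2.39 for SLC7A11, -2.26 for COLQ, -2.76 for PHB2, -2.88 for SELENBP1, -3.01 for TNS1 and -5.32 for ACSBG1. STC2 was at least 123-fold higher, with 276 counts against 0, and COLGALT2 had a ratio of 130. List medians were 6.29 for granulocyte and monocyte, 2.02 for mast cell, basophil and eosinophil, 1.29 for ATF4 targets, -0.17 for iron handling, -0.18 for ketone body and fatty acid oxidation, -0.21 for mitochondrial DNA maintenance, and -0.22 for the mitochondrial ribosome. They were -0.33 for import and quality control, -0.34 for the TCA cycle, -0.38 for G2 and mitosis, -0.41 for erythroid transcription factors, -0.46 for p53 targets, -0.51 for heme synthesis, -0.80 for erythroid membrane and -2.32 for globins and AHSP.

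Granulocyte and monocyte transcripts were higher in both shPHB2 libraries than in both shNT libraries. In shPHB2, LYZ stood at 2059 and 125 CPM, ELANE at 1524 and 130 CPM and MPO at 1350 and 107 CPM. They stood at 40.9, 28.9 and 44.6 CPM in shNT replicate 1 and at 5.27, 1.21 and 1.76 CPM in shNT replicate 2. These genes thus also differed together between the control libraries, which carried no hairpin against PHB2. A lower share of erythroid cells alone would raise all other lineages alike. The median log2 fold change of this list exceeded that of the megakaryocyte and platelet list by 4.30. Their quartiles did not overlap (3.41 to 5.59 against 0.23 to 1.66). Nor did they among the 11 and 13 members at 1 to 30 CPM in shNT (3.23 to 5.29 against -0.06 to 1.93). The mast cell, basophil and eosinophil list did overlap (1.61 to 6.10). The comparison can decide only if erythroid cells do not express the megakaryocyte and platelet genes themselves, which was not measured. All 17 members had at least 1 CPM in shNT, with ITGA2B at 136 and 102 CPM. Granulocyte and monocyte cells are a candidate source, which the CD34+ selection would not remove since it keeps their progenitors; of the list's 19 genes, 12 had at least 1 CPM in shNT and 0 are in another list. In shPHB2 100% of the 17 members with at least 20 counts in both libraries were higher in replicate 1, by a median of 3.06, but genes induced together would do the same, so cells and induction cannot be told apart. An effect of PHB2 loss may also be present and cannot be told apart from cultures that happened to differ, because the gap of 1.02 between the lowest shPHB2 and the highest shNT library median rests on 2 libraries against 2.

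Nuclear-encoded mitochondrial genes lay lower in both knockdowns. Bias by abundance or gene length may account for part of it, since 10000 lists matched on both centred at -0.08 and -0.15, but not for the whole: the pooled medians of -0.26 in shTFAM and -0.46 in shPHB2 lay below all of them (lowest -0.15 and -0.27). In shPHB2 the pooled mitochondrial median differed by only -0.0067 between the 2 libraries (-0.45 and -0.45). Their granulocyte and monocyte levels differed by 2.72 log2 CPM, which argues against dilution by such RNA as the whole cause. It cannot exclude dilution as a part, since replicate 2 also had the lower PHB2 level (37.0 against 64.0 CPM), which could offset it. Single lists moved in opposite ways, with medians of -0.17 and -0.41 for complexes II to V and -0.60 and -0.46 for import. In shTFAM the granulocyte and monocyte levels of 1.26 and 0.85 log2 CPM lay between those of shNT (2.58 and 0.57). Adjusting for that level could thus not take away a fall brought by dilution, and the covariate test cannot decide. With the covariate the pooled median was -0.27 (quartiles -0.42 and -0.13) and all 6 lists stayed called. Taken over all markers, the levels argue against 1 form of dilution as the whole cause in shTFAM, that by RNA with the marker mix of shPHB2 replicate 1. The needed share of such RNA was 20.7% and 12.7% in the 2 libraries. If shPHB2 replicate 1 were such cells alone, 14 and 13 of the 19 markers stood below the level this share would bring. The median shortfall over all 19 was 3.87 and 3.53 log2. The others reached that level, CST3 and CYBB in shNT already. CD68 (42.5 and 33.7 CPM, needed 16.2 and 9.91) and CTSS (18.8 and 8.59 CPM, needed 12.2 and 7.42) also lay above both shNT libraries. In shNT they stood at 11.4 and 8.45 CPM and at 5.69 and 2.30 CPM. Dilution as a part, or by such RNA with another mix of markers, thus stays open. The shared shNT pair may itself stand apart: its 2 libraries differed by 0.0047, but no second control group was measured, so this cannot be told apart from an effect of both hairpins.

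The 2 libraries of each knockdown lay further apart than the 2 shNT libraries, with 746 genes over 2-fold apart in shTFAM and 1165 in shPHB2 against 99 in shNT, among genes with at least 40 counts over the pair. Depth does not account for it: after thinning all libraries to 4726644 counts the numbers were 638, 1138 and 61, at least 10.5 times as many in a knockdown pair. Unequal granulocyte and monocyte content was measured by the median of that list. Its difference between the shTFAM libraries minus that between the shNT libraries was -1.60 log2 CPM. The median lay low in shTFAM (1.26 and 0.85 log2 CPM), and single markers differed. CST3 stood at 237 and 125 CPM against 145 and 130 in shNT, and SPI1 at 10.2 and 2.08 against 4.78 and 2.41. AZU1 went the other way, at 1.85 and 1.94 CPM against 27.3 and 1.21. The median thus argues against unequal content in shTFAM only for the list as a whole. In shPHB2 the same difference was 0.71 (2.72 against 2.01). With 1 pair per group such content cannot be told apart there from other differences between cultures. Different hairpins or unequal knockdown in the libraries named sh1 and sh2 may underlie the spread; the target differed at least 1.73-fold between the 2 libraries (1.78-fold for TFAM), but with 1 library each this cannot be told apart from variation between cultures.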

How the results depend on the processing

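The library-weighted voom fit, the granulocyte and monocyte covariate and cyclic loess were chosen after seeing the data; the other alternatives were fixed before. Except where an alternative's construction shows it (fewer libraries, a stricter threshold), the cause of a change was not tested. Counted once per list, comparison and alternative, 64 results gained a call, 124 lost one and 12 turned direction with a call on either side, while 1090 kept their status. The results that turned are counted apart, although some of them also gained or lost a call. Counted once per named gene, comparison and alternative, 39 results gained a call, 456 lost one, 0 turned with a call on either side and 1612 kept their status. Depth limits genes with few control counts such as ASS1.

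For shTFAM against shNT, the 1 call became 83 without a filter on low counts, 457 with DESeq2, 0 with log2(RPKM + 1) and log2(RPKM + 0.1), 10 with the RPKM filter (4 higher, 6 lower), 2 with the 2 groups only, 269 with library weights, 53 with the granulocyte and monocyte covariate, 0 with cyclic loess and 0 at an adjusted p under 0.01. Leaving out single libraries gave 0 to 2. For shPHB2 against shNT, the 1997 calls became 130 with the 1.5-fold test, 1 with the covariate, 0 at an adjusted p under 0.01 and 1126 with a 2-fold minimum. Single libraries left out gave 0 to 3682. DESeq2 called 2935 genes, and at an unadjusted p under 0.05 edgeR counted 4864. The covariate follows the shPHB2 group closely and takes a degree of freedom, so a call lost under it is not a sign that the gene did not change. Of lists, S phase and mast cell, basophil and eosinophil lost their call with it in shPHB2, and G2 and mitosis kept its call (0.00998). In the direct contrast erythroid membrane, erythroid transcription factors, heme synthesis, import, mitochondrial DNA maintenance, the TCA cycle, ketone body oxidation, iron handling and p53 targets lost it, at 0.0610 to 0.968, and complexes II to V, glycolysis and cholesterol synthesis gained one, as did stem and progenitor cell and the cytosolic ribosome in shTFAM. For shPHB2 against shTFAM, the 31 calls became 19 with upper-quartile scaling, 171 without a filter, 839 with DESeq2, 0 with limma-voom, 1 with the 1.5-fold test, 10 with log2(RPKM + 1), 1 (lower) with log2(RPKM + 0.1), 0 with the 2 groups only, 0 with library weights, 0 with the covariate, 50 with cyclic loess and 0 at an adjusted p under 0.01. Single libraries left out gave 0 to 534.

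The 1 gene called in both knockdowns became 65 without a filter, 353 with DESeq2, 0 with either log2(RPKM) scale, 8 with the RPKM filter, 189 with library weights, 0 with the covariate, 0 with cyclic loess and 0 at an adjusted p under 0.01, and 0 to 2 with single libraries left out. TFAM in shTFAM passed the threshold without a filter (-3.01, adjusted p = 0.0147), with DESeq2 (-3.01), with library weights (-3.05, 0.0221) and with the covariate (-2.98, 0.0352). Its log2 fold change ran from -3.49 to -2.63 with single libraries left out. Over all alternatives its adjusted p ran from 2.92e-19 to 0.916. PHB2 in shPHB2 missed it with the covariate (-3.64, adjusted p = 0.0836) and without either shNT library, its adjusted p ran from 9.56e-24 to 0.256, and its log2 fold change ran from -3.44 to -2.64 with single libraries left out.

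Leaving out a shNT library ends every edgeR call in the 3 comparisons. The lone shNT library is then assumed to vary like the knockdown libraries, whose spread is wider. The calls may thus rest on the closeness of the 2 shNT libraries, but the loss of a residual degree of freedom was not told apart from it. Lists called by camera numbered 11, 18 and 15 in the 3 comparisons, 0, 0 and 0 with an estimated correlation and 0, 6 and 0 with fry.

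Lists that turned direction are given with the adjusted p then reached. In shTFAM, with single libraries left out, they were granulocyte and monocyte (0.0245 without shNT replicate 1, range 0.00011 to 0.980), megakaryocyte and platelet (0.424 without shNT replicate 2, range 2.33e-07 to 0.424), erythroid membrane (0.00168 without shTFAM replicate 1, range 0.00047 to 0.945) and globins (0.00447 without shTFAM replicate 2, range 4.84e-11 to 0.556). In shPHB2 the cytosolic ribosome turned without shPHB2 replicate 1 (0.709, range 2.21e-05 to 0.709). With the covariate, megakaryocyte and platelet (3.69e-06) and the cytosolic ribosome (0.0175) turned in shPHB2. In the direct contrast megakaryocyte and platelet (1.08e-17), mast cell, basophil and eosinophil (0.968), S phase (1.74e-06), G2 and mitosis (0.0199) and the cytosolic ribosome (1.91e-05) turned.

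The labels give every group the same replicate numbers. Deviations of same-numbered libraries correlated across genes at 0.26 between shNT and shTFAM, 0.41 between shNT and shPHB2 and 0.37 between the knockdowns, but with 2 numbers this does not show pairing. With the replicate block, edgeR called 307, 3590 and 767 genes in the 3 comparisons and 266 in both knockdowns, and TFAM in shTFAM passed the threshold (-3.01, adjusted p = 0.0128).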

Other observations

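The tests of how genes called in shPHB2 lay in shTFAM were chosen only after the result was seen. The genes named here were chosen after their values were seen.

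Several lists that were not called in shPHB2 held members that changed in both directions by the edgeR test, although 0 genes were called without either shNT library. Among NRF2 and antioxidant genes, HMOX1, which degrades heme, rose by 2.82 on the log2 scale, OSGIN1 by 3.11 and NQO1 by 1.88, while the peroxiredoxins PRDX2 and PRDX3 fell by 1.86 and 0.68 and SOD1 fell by 0.54. Among iron genes, FTL, the ferritin light chain, rose by 0.86, while NFS1, BOLA3 and FDXR, which serve iron-sulphur cluster assembly, fell by 0.96, 1.13 and 0.95. Of hypoxia-inducible genes, VEGFA rose by 1.84, NDRG1 by 1.72, KDM3A by 1.01 and PDK1 by 0.85, and MXI1 fell by 0.58. In glycolysis ENO2 and ALDOC rose by 1.22 and 0.97, and PKLR, the pyruvate kinase of red cells, fell by 1.66. Of stem and progenitor genes, FLT3 and ERG rose by 5.52 and 3.61, while NPR3, MLLT3 and CD164 fell by 1.91, 1.24 and 0.79. FLT3 stood at 75.5 and 9.37 CPM in the shPHB2 libraries and ERG at 7.04 and 1.72.

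The libraries of a knockdown did not rank alike on all readouts. In shPHB2, replicate 2 had the lower PHB2 level (37.0 against 64.0 CPM) and the higher ATF4 median (1.70 against 0.71), whereas replicate 1 had the lower globin median (-2.37 against -1.70) and the higher granulocyte and monocyte median. In shTFAM, replicate 1 had the lower TFAM level (13.9 against 24.8 CPM), the lower S phase median (-0.86 against -0.30) and the lower globin median (-0.71 against 1.43). The S phase median was also lower in replicate 1 of shPHB2 (-1.22 against -0.33), and the ATF4 median in replicate 1 of shTFAM (-0.31 against 0.05). The S phase, globin and ATF4 medians thus ranked by replicate number in both knockdowns, and not by the level of the target. Other lists did rank by that level. In replicates 1 and 2 the complex I median was -0.34 and -0.14 in shTFAM and -0.34 and -0.41 in shPHB2. For complexes II to V it was -0.33 and -0.18, and -0.17 and -0.41. The mitochondrial ribosome and import medians were lower in replicate 1 of both knockdowns. These are values of single libraries with no test.

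Some genes lay at nearly the same low level in both knockdowns. DOCK9 had log2 fold changes of -3.11 and -3.09 in shTFAM and shPHB2, and TRIM29 of -3.28 and -3.65. LAT lay 1.70 and 1.66 higher. Of the 1997 genes called in shPHB2, 547 of those that rose (51.0%) and 420 of those that fell (45.5%) had an unadjusted p under 0.05 in the same direction in shTFAM, and 2 and 11 in the opposite direction (0.186% and 1.19%). In 100 simulations with shTFAM unchanged and the shNT libraries shared, these shares were 6.21% and 4.98% in the same direction and 2.97% and 1.34% in the opposite direction. These simulations gave a gene the same spread in every library, although the shNT pair was closer, and called more genes in shPHB2. Their shares are thus only a rough guide.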
